A study of Mus musculus with 16 samples.

How the data were processed

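The series used microarrays to ask which odorant receptors are expressed by olfactory sensory neurons that respond to bourgeonal, an aromatic aldehyde with a lily of the valley smell. The mice carried an S100a5-tauGFP reporter, per the labels. S100a5 is a calcium-binding protein whose expression in olfactory sensory neurons rises with activity, so GFP is meant to mark active neurons. Per the labels' protocols, 24 C57BL/6 mice of both sexes, aged 7 to 12 weeks, spent 40 hours alone in clean air chambers at 3.1 L/min. From hour 26 they received 10 second pulses of odorant or filtered air every 20 minutes. Olfactory mucosa was dissociated and sorted by fluorescence, and cRNA was made from 50 to 100 ng of RNA for Clariom S arrays. The labels name 3 mice per library, which gives 8 pools, 4 per treatment, with a GFP+ and a GFP- library each. The 16 libraries fall into 4 groups of 4.

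For all 16 samples the title and the cell type field name opposite gates. Groups follow the titles, so libraries are called titled GFP+ and titled GFP-. Gate ratios are given as titled GFP- over titled GFP+, because S100a5 was higher on that side. This is the opposite sign of the direction in which the comparisons were first written.

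The values analysed are the deposited log2 expression values, which the authors made with Affymetrix Expression Console, per the submitters' processing notes. The version, the summarisation method and the genome build are not given in the sources used here. The log base was read from the hybridisation spike-ins, whose mean values were 8.60 for bioB, 10.44 for bioC, 11.64 for bioD and 13.31 for cre. The median over all probe sets lay between 5.40 and 5.65 in the 16 libraries. Arrays have no read depth, so their number limits the precision, and signal near background compresses ratios. Vomeronasal receptor genes served as a guide to background: their 95th percentile lay between 4.29 and 4.97.

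Of 28846 probe sets, 94 spike-in and background controls and 6546 with neg or pos in their ID were left out as controls. Of the rest, 19572 named 1 gene, 0 named several and 2634 named none in the annotation used here. For genes with several probe sets the one with the highest mean over all libraries was kept, which left 19505 genes and set 67 probe sets aside. All Entrez IDs (100%) matched the reference gene table (GRCm38.p6), which was used for chromosomes, gene order and the gaps between neighbouring receptors. No coordinates are given. No probe set was named Xist or Ddx3y. Probes for receptors can also bind near-identical family members, which was not tested.

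Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes). One fit of all 16 libraries with the pool as a block gave the gate ratio in vehicle pools, the gate ratio in odor pools and their difference, odor minus vehicle. Odor was also compared with vehicle within each gate on 8 libraries without a block. All tests were two-sided, with Benjamini-Hochberg adjustment over 19505 genes and a threshold of 0.05. For the 1090 odorant receptors the count adjusted over the list alone is given too. Of 26 gene lists, 25 had measured members; the list of class I receptors was empty because the annotation uses the older Olfr symbols. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 25 lists. Single values were tested with exact permutation or sign-flip tests over pools.

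The comparisons, the gene lists, the first set of alternatives and the rule for named genes were fixed before the data were examined. For the difference and for odor in libraries titled GFP+, the rule named up to 10 receptors that rose and 5 that fell past the threshold over the list alone, filled up to 10 by the smallest p and given as not passing. It also allowed 5 other genes each way past the threshold over all genes. For the other comparisons it named the 8 largest rises and falls past the threshold, leaving out odorant receptors and Gm and Rik genes. It added up to 4 members of each list, by order, and S100a5, Omp, Kirrel2, Kirrel3 and Xist. Genes outside the rule are said to be so.

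The gates of a pool were treated as paired because they come from the same mice, which was inferred from the count of mice. Deviations from the group means correlated at 0.135 to 0.287 between the gates of an odor pool and at 0.098 to 0.201 in vehicle pools. Odor and vehicle libraries of the same number correlated at 0.157 to 0.210 among libraries titled GFP+, so numbers were taken as paired there and the blocked result is given beside the main one. The labels do not say what a shared number stands for. Pearson correlations between libraries of a group were 0.9896 to 0.9944.

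The fits were tested on simulated data over 19505 genes with 200 changed. For the odor minus vehicle difference they recovered 34.3% of genes changed by 1 on the log2 scale, 80.6% of those changed by 2 and 100% of those changed by 4. For odor in libraries titled GFP+ the shares were 59.7%, 95.5% and 100%, and for libraries titled GFP- 46.3%, 89.6% and 100%. False calls were 4 of 147 for the difference, 11 of 181 for titled GFP+ and 5 of 162 for titled GFP-. They were 11 of 189 for the gate ratio in vehicle pools and 14 of 194 in odor pools. The simulated noise was independent between genes, and 200 changed genes make the adjusted threshold easier to reach. These shares therefore do not carry over to data in which only a few genes change. Alternatives covered normalization, scaling, a filter on dim probe sets (above the 40th percentile in at least 4 libraries), the variance prior, library weights, blocks, a sex covariate from Y-linked genes and leaving out each pool. Including unnamed probe sets and leaving out number 4 of both treatments were added after seeing the data. In the tests of explanations, both tests of the second principal component first written were kept as worded, and 2 further ones were added after its order was known. Sex composition as a source of the Olfr16 difference was tested, after that difference was seen, by the balance of the Y-linked mean between the treatments and with that mean as a covariate of the gate ratio of the 8 pools. List tests were not run with the trend and robust prior or with random blocks.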

Results

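Expression was measured in sorted olfactory mucosa cells from mice that had received pulses of bourgeonal or filtered air. There were 4 odor pools and 4 vehicle pools of 3 mice, each with a library titled GFP+ and a library titled GFP-, and all values are deposited log2 values. The first principal component held 69.1% of the variance and separated the gates. The second held 4.8%.

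S100a5, the gene whose reporter drives the GFP, was higher in the library titled GFP- in 8 of 8 pools. The mean log2 ratio of titled GFP- over titled GFP+ was 1.02 ± 0.25 (SD, n = 8 pools), with a range of 0.65 to 1.46 (exact two-sided sign-flip test, p = 0.00781, the smallest that 256 flips allow). This goes against the titles and with the cell type field, which names the opposite gate for every sample. Every direction below is therefore given for the library as titled.

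**Figure D1:**
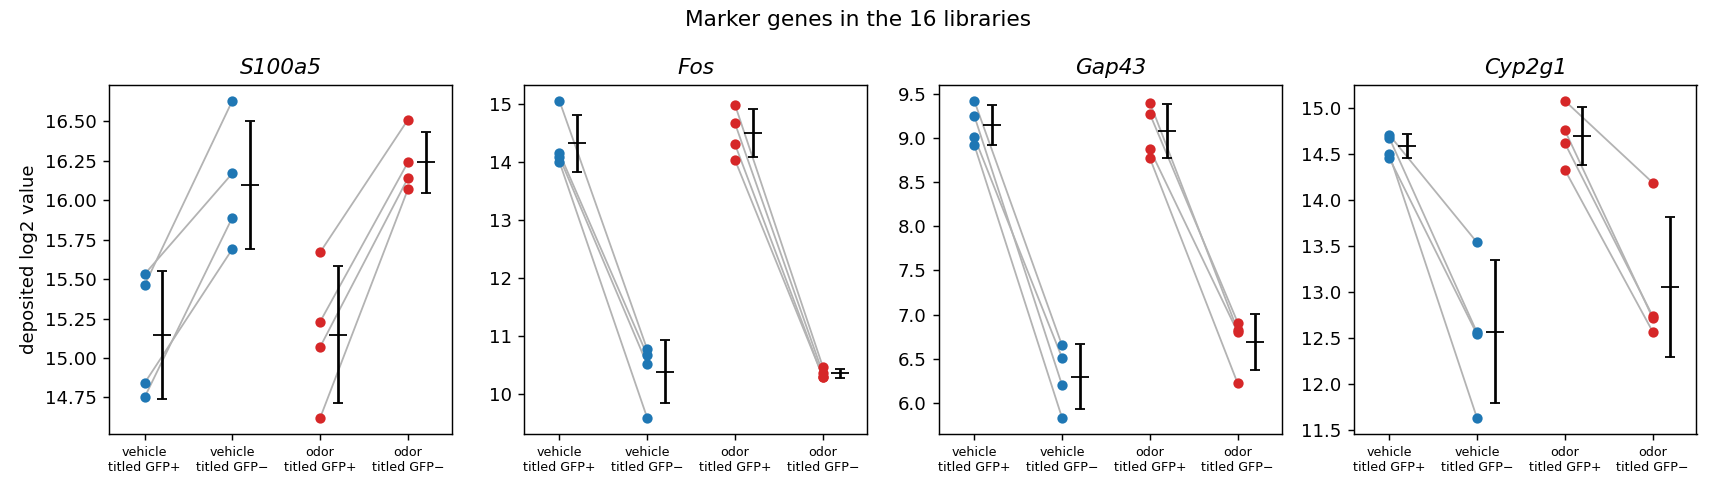
Deposited log2 values of S100a5, Fos, Gap43 and Cyp2g1 in each of the 16 libraries, by treatment and titled gate. Points are libraries, grey lines join the gates of a pool, and black marks are the mean and SD of 4 libraries; S100a5 was higher in the library titled GFP- in 8 of 8 pools, while the other genes were lower.

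The gate ratio in vehicle pools asked what the sort separated without odor. Libraries titled GFP- held more RNA of activity-linked neuronal genes and less of immune, microvillar, supporting and immature cells. Of 8 measured activity-induced genes of sensory neurons, 7 were higher, including Kirrel2 (log2 1.11), an adhesion molecule that sorts axons by activity, Pcdh10 (1.08) and Lrrc3b (1.71). The list was higher as a whole (camera, adjusted p = 1.04e-05, and adjusted p = 0.0493 with an estimated correlation). It holds S100a5, whose reporter was sorted and whose side set the direction of the ratio, so that member is not independent support. Kirrel3, an adhesion molecule of less active neurons, was lower with the pool as a block (log2 -0.54, limma adjusted p = 0.0242), as was the calcium-binding protein Calb2 (-4.64). That list of 5 low-activity genes was lower by camera (adjusted p = 0.0136), but had an adjusted p = 0.217 with an estimated correlation. Omp, the marker of mature olfactory sensory neurons, had a log2 ratio of -0.02 and did not pass. Its values in the 16 libraries, 18.63 to 18.97, lay near the highest values of the arrays, 19.38 to 19.59. Its ratio may be compressed there, so it does not show an equal content of mature neurons in the gates. Of 20 mature neuron genes, 4 were higher and 0 lower. That list had an adjusted p = 0.0319, and adjusted p = 0.217 with an estimated correlation. Of 17 transduction and adaptation genes 5 were higher and 2 lower (camera adjusted p = 0.267). Without the pool block neither Kirrel2 (limma adjusted p = 0.145) nor Kirrel3 (0.174) passed, and Kirrel3 did not pass without vehicle pool 2 (0.0631), 3 (0.0998) or 4 (0.108).

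Genes of other cells were lower in the libraries titled GFP-. All 16 immune genes were lower (adjusted p = 5.21e-23, and adjusted p = 0.0284 with an estimated correlation). Outside the odorant receptors and the genes without a proper name, the 8 largest measured falls were in neutrophil and myeloid genes: Lcn2 at a log2 ratio of -11.49 ± 0.34 (SE), Ngp at -11.22, Retnlg at -10.11, S100a8 at -9.13, Ly6c1 at -8.70, S100a9 at -8.57, Ly6c2 at -8.53 and Chil3 at -8.27. All 12 microvillar cell genes were lower, among them the channel Trpm5 (-4.46) and the transcription factor Foxi1 (-5.36). Of 14 genes of sustentacular cells, the supporting cells of the epithelium, 9 were lower, including the cytochromes Cyp2g1 (-2.02) and Cyp2a5 (-2.48). Of 11 progenitor genes 9 were lower, with the proliferation marker Mki67 at -5.38. Of 15 immature neuron genes 9 were lower, with the growth cone protein Gap43 at -2.85 and Gng8 at -4.72. Both erythroid genes measured, Alas2 (-1.27) and Slc4a1 (-2.29), were lower. That list had an adjusted p = 0.00462, and adjusted p = 0.128 with an estimated correlation. The titled GFP- means of Retnlg, S100a8, Ly6c1, S100a9, Ly6c2, Trpm5 and Mki67 lay below 4.97, the highest 95th percentile of vomeronasal genes in those libraries. Their ratios are therefore lower bounds on the size of the fall and have no order among themselves.

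Immediate early genes were also lower in the libraries titled GFP-: 14 of 20 passed, with Fos at a log2 ratio of -3.94, Fosb at -3.11 and Fosl2 at -1.67. The list had an adjusted p = 6.9e-14, and adjusted p = 0.019 with an estimated correlation. These genes moved with the immune and supporting cell genes, opposite to S100a5. Of 7 heat shock genes 4 were lower, including Hspa1a (-1.29), which did not pass without the pool block (limma adjusted p = 0.46). Of 8 genes of guanylyl cyclase D neurons 5 were lower, with the phosphodiesterase Pde2a at -3.63. Of 8 endothelial genes 0 passed, of 13 unfolded protein response genes 0 passed, and of 7 stromal genes only Dcn (-0.85) did. Both gate means lay below background for 8 of 8 endothelial, 5 of 6 horizontal basal cell, 5 of 7 ensheathing glia, 5 of 9 Bowman's gland, 4 of 7 stromal, 3 of 7 respiratory cilia and 2 of 8 guanylyl cyclase D neuron genes. Of the genes counted as lower, this held for the progenitor genes Neurog1 and Cdk1, the microvillar gene Chat and the heat shock gene Hspb1. Cdk1 and Chat fall outside the naming rule. Bowman's gland genes were mixed, with Sox9 lower (-4.88) and 6 of 9 not passing; Obp1a passed as higher (0.80), but both of its means lay below that background. Of 7 ensheathing glia genes 1 was lower, Apoe at -2.97. Of 15 synaptic vesicle genes 3 were higher, of 7 respiratory cilia genes 1 and of 6 horizontal basal cell genes 1. Of 3 sex-linked genes 0 passed. By camera 13 of the 25 lists passed, and those of low-activity, mature neuron and erythroid genes lost the call with an estimated correlation. These lists passed by fry, at adjusted p = 6.76e-05, 0.000242 and 0.000541.

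Chemoreceptor genes went both ways. The rises outside the odorant receptors were led by Fxyd2, a sodium pump regulator, at a log2 ratio of 2.95, and by the trace amine receptors Taar9 (2.89), Taar4 (2.84) and Taar3 (2.58). Lrrc3b, Galnt15 (1.66), Caly (1.56) and Pcp4l1 (1.52) followed. Of 14 trace amine receptors 7 were higher and 4 lower (camera adjusted p = 0.138). Of 319 vomeronasal receptors, which served as the guide to background, 309 had both gate means below it. That share is largely fixed, because the guide is their own 95th percentile. Over all genes 15 passed as higher, 14 of them with both means below background, and 0 when adjusted over the list alone (camera adjusted p = 0.000183, and adjusted p = 0.0493 with an estimated correlation). Their median lay at 3.42 to 3.57 in all libraries titled GFP- and at 3.19 to 3.36 in all titled GFP+. The list call may therefore be an offset of the background between the gates. Of 1090 odorant receptors, 388 were higher and 298 lower over all genes, and 446 and 338 when adjusted over the list alone. Over all genes, 3156 passed (limma): 1216 higher and 1940 lower. Of these, 403 and 1299 differed by more than 2-fold. With each library centred on its own median, 53.1% of calls were higher against 38.5% as deposited.

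The gate ratio in odor pools asked the same with bourgeonal. S100a5 had a log2 ratio of 1.09 (limma adjusted p = 0.000282) and Kirrel2 of 1.00. Kirrel3, at -0.27, did not pass, and its ratio did not differ between the treatments past the threshold (limma adjusted p = 0.888). Without the pool block Kirrel2 did not pass in odor pools either (limma adjusted p = 0.182). Again 7 of 8 activity-induced genes were higher, with Pcdh10 at 1.66. Of the immune genes 15 of 16 were lower, of the microvillar genes 12 of 12, of the sustentacular genes 10 of 14 and of the immediate early genes 15 of 20, with Fos at -4.14. Outside the receptors the 8 largest measured falls were the neutrophil and myeloid genes named for vehicle pools, with Lcn2 at -11.71; those of Retnlg, S100a8, Ly6c1 and Ly6c2 are again bounds. Taar7b (1.85) and the potassium channel Kcng1 (1.69) were among the 8 largest rises. Over all genes 3521 passed, 1526 higher and 1995 lower. In both treatments 696 genes were higher, against 95.1 for independent lists, and 1641 lower, against 198.4. Both lists come from the same kind of sort and a shared fit. An overlap above independence was therefore likely in advance and is not a test. By camera 14 lists passed. With an estimated correlation the call was lost for low-activity genes (adjusted p = 0.269), mature neuron genes (adjusted p = 0.145), erythroid genes (adjusted p = 0.112), heat shock genes (adjusted p = 0.112), synaptic vesicle genes (adjusted p = 0.313) and vomeronasal receptors (adjusted p = 0.11). All of these lists passed by fry, with a largest adjusted p = 0.00151. Centring each library on its median gave 6968 genes, 75.5% of them higher against 43.3% as deposited, and moved the median log2 ratio of all genes from 0.105 to 0.301.

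Odorant receptors kept nearly the same place between the gates with and without odor. Across the 1090 receptors, which are not independent replicates, the gate ratios of the treatments had a Pearson correlation of 0.982 and a Spearman correlation of 0.973. In odor pools 427 were higher and 290 lower, and 472 and 329 when adjusted over the list alone.

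**Figure D2:**
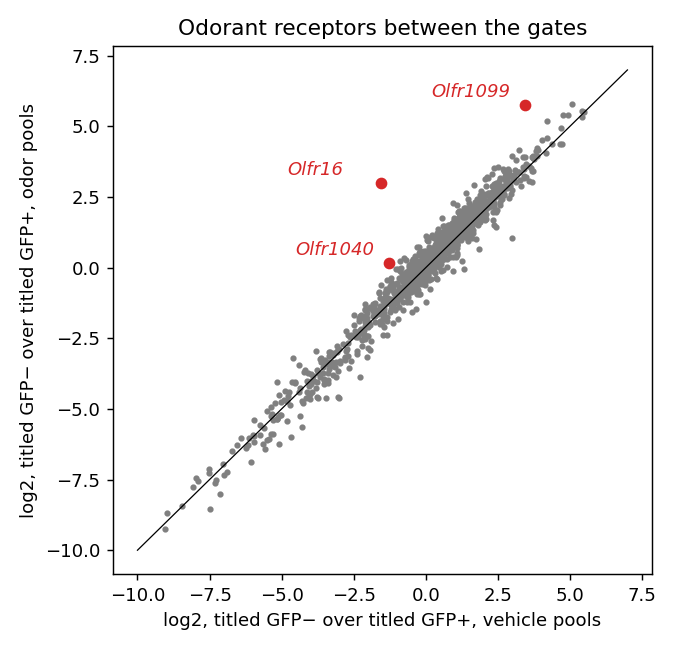
Log2 ratio of titled GFP- over titled GFP+ for 1090 odorant receptors in vehicle pools (horizontal) and odor pools (vertical); each point is a receptor and the line marks equal ratios. Most receptors lie near the line (Pearson correlation 0.982), and Olfr16, Olfr1099 and Olfr1040 (red) lie above it.

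The odor minus vehicle difference of the gate ratio asked which receptors move with bourgeonal towards the libraries titled GFP-, the side with more S100a5. Olfr16, also known as MOR23 and described as a receptor for the lily of the valley odorant lyral, moved most. Its log2 ratio was -1.55 ± 1.52 (SD, n = 4 pools) in vehicle and 3.01 ± 1.16 in odor, a difference of 4.57 (95% interval 2.90 to 6.23). Its level went from 9.13 to 11.73 in the libraries titled GFP- and from 10.68 to 8.71 in those titled GFP+, as group means. Neither change passed in the main fits within a gate. Olfr1099 went from 3.44 ± 0.59 to 5.78 ± 0.61, a difference of 2.34. Olfr1040 went from -1.28 ± 0.30 to 0.18 ± 0.22, a difference of 1.46, but its group means, 2.79 to 4.20, lay below the 95th percentile of vomeronasal genes. For each of the 3, all 4 odor ratios lay above all 4 vehicle ratios (exact permutation p = 0.0286, the smallest that 70 assignments allow). They were picked from 1090 receptors by this same difference, so that p is not independent evidence.

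**Figure D3:**
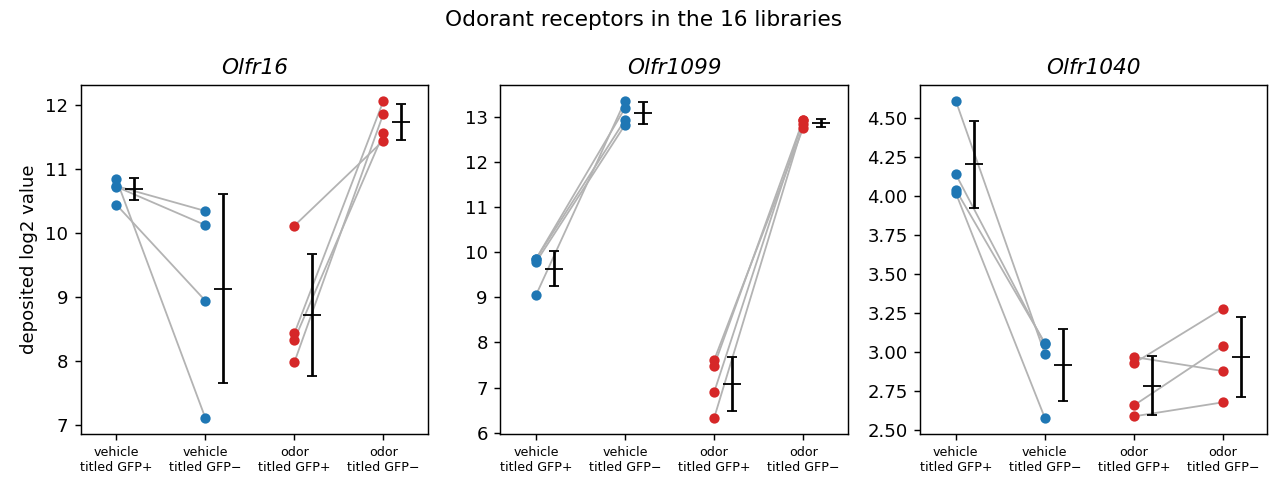
Deposited log2 values of Olfr16, Olfr1099 and Olfr1040 in each of the 16 libraries, by treatment and titled gate. Points are libraries, grey lines join the gates of a pool, and black marks are the mean and SD of 4 libraries; Olfr16 was lower in the library titled GFP- in 4 of 4 vehicle pools and higher in 4 of 4 odor pools.

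These 3 receptors passed when adjusted over the list alone, with limma adjusted p of 0.0397 for Olfr16, 0.0322 for Olfr1099 and 0.0301 for Olfr1040. Over all genes 0 passed in limma (smallest adjusted p = 0.172), with 1109 genes at an unadjusted p under 0.05 against 975 expected by chance. The next receptors did not pass: Olfr198 (difference 1.12), Olfr1151 (1.16), Olfr1115 (1.10), Olfr516 (1.20), Olfr738 (1.35), Olfr1279 (-1.11) and Olfr1372-ps1, with a limma adjusted p over the list alone of 0.331. Olfr516, Olfr738 and Olfr1279 lay below background in 1 gate. The median difference of all receptors was 0.126. S100a5 differed by 0.14 (exact permutation p = 0.514), and 0 of the 8 activity-induced genes passed. Immediate early genes had a median difference of -0.30 (camera adjusted p = 0.000767, and adjusted p = 0.622 with an estimated correlation). They did not pass by fry (adjusted p = 0.29). No other list passed by camera, and none passed by fry. Without odor pool 2, 3 or 4 or vehicle pool 2, 0 receptors passed, and 1 did without vehicle pool 1 (Olfr1040) or 3 (Olfr738). None of the 3 receptors passed without vehicle pool 3, each with a limma adjusted p over the list alone of 0.0533. With dim probe sets left out 0 passed, and with the number as a block across treatments 5 receptors and 1 gene over all genes did.

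Odor against vehicle within the libraries titled GFP+ compared the cells on that side of the sort. Olfr1099 was lower with odor (log2 -2.55, limma adjusted p = 0.0345) and so was Olfr1040 (-1.41, adjusted p = 0.0483). These were the 2 genes past the threshold, over all genes and over the list alone alike. Olfr16 had a log2 change of -1.97 and did not pass (limma adjusted p = 0.0712 over the list alone). Other receptors that did not pass were Olfr1186 (-1.69), Olfr1100 (-1.02), Olfr979 (-0.61), Olfr740 (-0.76), Olfr1352 (-0.73), Olfr576 (-0.86) and Olfr1301 (-0.94). The odor means of Olfr1186 (4.36) and Olfr576 (4.04) lay below the background of 4.57, so their changes are bounds. Olfr1040 lay below background in both treatments, with 4.02 to 4.61 in the vehicle libraries against 4.64 and a mean of 2.79 with odor. Its call therefore rests on signal near the floor. Immediate early genes were higher as a list, with a median of 0.24 (camera adjusted p = 9.8e-06, and adjusted p = 0.698 with an estimated correlation). The odorant receptors had a median of -0.09 (adjusted p = 0.016, and adjusted p = 0.752 with an estimated correlation). Neither of these lists passed by fry (adjusted p = 0.77 for each). With the replicate number as a block, only Olfr1099 passed over all genes (limma adjusted p = 0.00211), Olfr1040 did not (0.0911), and 8 receptors passed over the list alone, Olfr16 among them (0.0403). Over all genes 0 passed without odor pool 2 or 3 or vehicle pool 1, 2 or 3, and 1 without odor or vehicle pool 4; over the list alone 5 receptors passed without odor pool 1 or vehicle pool 3.

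Odor against vehicle within the libraries titled GFP- showed 0 genes past the threshold in limma, with 869 at an unadjusted p under 0.05 against 975 expected by chance. When adjusted over the list alone 2 receptors were lower, Olfr374 and Olfr1220, each with a log2 change of -1.10 (limma adjusted p = 0.0492), although the mean of Olfr374 in odor pools, 4.20, lay below the background of 4.90, so that its change is a bound. They fall outside the naming rule and were chosen after their values were seen. Olfr16 had a log2 change of 2.60 (limma adjusted p = 0.145 over the list alone) and Olfr1099 of -0.21 (0.835). With the mean of the Y-linked genes as a covariate Olfr16 passed over the list alone (limma adjusted p = 0.0341, against 0.0341 to 0.292 over all alternatives). With the replicate number as a block, 12 receptors passed over the list alone. Olfr16 was among them (limma adjusted p = 0.044, and 0.626 over all genes). Numbers were not taken as paired in these libraries, because their correlations, 0.088 to 0.161, were not all above the bound for pairing. Every library still correlated best with its own number. The gates of a pool were taken to hold the same mice, so a pairing in libraries titled GFP+ would extend to these. Whether Olfr16 passes over the list alone here therefore depends on that choice. S100a5 had a log2 change of 0.14 (limma adjusted p = 0.996), and 0 of the 25 gene lists passed. With any 1 of the pools left out, 0 or 3 receptors passed: 3 without odor pool 2 or vehicle pool 3, the latter without Olfr1220, and 0 without odor pool 1, 3 or 4 or vehicle pool 1, 2 or 4.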

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

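The tests of a sex or session difference and of sex composition for Olfr16, of the order of the replicate numbers and of correlations within a number were chosen after the result was seen.

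The odor minus vehicle difference of the gate ratio was 4.57 for Olfr16, 2.34 for Olfr1099 and 1.46 for Olfr1040, each a tested difference between the treatments. For Olfr16 a shift of all receptors between the gates was tested by centring each library on its receptors: the difference stayed at 4.43, against a median of 0.13 over all receptors, which argues against it. The ratio was higher in odor in 4 of 4 replicate numbers, with differences from 2.82 in number 1 to 6.94 in number 4. The separation of the 4 odor from the 4 vehicle ratios fixes that outcome, so it says nothing about a difference in sex or session. Sex composition as the whole source is argued against by its balance, since the mean of the Y-linked genes differed by 0.06 between the treatments, against an SD of at least 2.76 over pools; as a covariate it left the difference at 4.55 but moved no receptor by over 0.03, so that test decides nothing. What stays open is a difference in session, chance, binding of the probes to related receptors and a response of the neurons to bourgeonal, any of which may be the source.

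Chance was tested by regrouping. Of the 35 splits of the 8 pools, 3 gave at least the real 3 receptors in the difference, and the highest other gave 43. For odor in libraries titled GFP+, 5 of 35 splits gave at least the real 2 receptors, with 67 as the highest other. In libraries titled GFP- it was 6 of 35, with a real count of 2 and 53 as the highest other. So chance cannot be excluded for these 3 counts. The high counts came from splits that set whole numbers apart, which points to a structure of the samples. Numbers 1 and 4 against 2 and 3 gave 43, 67 and 53. That split also parts low from high means of the Y-linked genes. These lay at 2.97 to 3.45 in number 4 and 6.96 to 7.40 in number 1, against 8.89 to 9.55 in numbers 2 and 3. Number 4 thus had no Y-linked signal above the guide to background. Numbers 1 and 2 against 3 and 4, a split that does not follow that mean, gave 33, 26 and 10. Numbers 1 and 3 against 2 and 4 gave 0 in all 3 comparisons. In the difference, the other splits that reached the real count all set whole numbers apart. Of the 8 splits that part every number, as the real one does, the real one alone reached its count in all 3 comparisons. The highest other gave 1 in the difference and 0 within either gate, but 8 splits are too few for a share under 0.05. The gates were regrouped in fits of the 8 libraries of each treatment without the pool block. In vehicle pools 1 of 35 splits gave at least the real 2601 genes (highest other 0). In odor pools 1 of 35 gave at least the real 2803 (highest other 2). That share bears on chance only for unpaired libraries, and the gates of a pool were treated as paired, so no conclusion on chance is drawn from it. Among the 8 splits that part the gates of every pool, the real one alone reached its count in each treatment (highest other 0). Those 8 are again too few for a share under 0.05.

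Libraries of one number also lay together on the second principal component, at -26.3 to -17.3 for number 4, -13.2 to -4.6 for 1, 8.6 to 15.0 for 2 and at least 17.2 for 3, but the gates of a pool lay at most 3.3 apart on it, so it is not shown to give the high counts in the gate ratio. Without the 830 genes of the X and Y chromosomes it still followed the mean of the Y-linked genes over the 8 pools (exact permutation p = 2.48e-05, the smallest possible), and the order of the numbers matched that mean in 4 of 4 groups, on 18675 genes. That test took the 8 pools as exchangeable, but the odor and vehicle pools of a number were alike in both measures, so its p overstates the evidence. The 4 groups share the same numbers and are not independent either. The pools also fall into separate clusters of the Y-linked mean, with a gap of 0.58 of its range, so no correlation is given and sex composition and number cannot be told apart. For a shared session, pools of numbers 2 and 3, alike in the Y-linked mean, lay at least 5.6 apart across numbers, but pools of one number lay up to 8.1 apart, so that test left a session open, and by correlations 4 of 4 such odor libraries were closer to the vehicle library of their own number, once only by 0.081 against 0.072. Sex composition and a shared session or litter may both contribute.

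S100a5 ran against the titles. If the titles carry the opposite gate, markers of other cells should be lower in the libraries titled GFP-, and their median over 38 immune, endothelial, stromal and ensheathing glia genes was -0.46 over the pools, at most -0.37 in any of the 8. With the titles right and S100a5 RNA lower in cells that hold the GFP, that median should lie above 0, so the value argues against it, but within those 38 it rests on the immune genes: medians per pool lay between -0.34 and 0.15 for endothelial, -0.24 and 0.37 for stromal and -0.25 and 0.17 for ensheathing glia genes, with endothelial levels near background. Outside that test, medians were below 0 in 8 of 8 pools for microvillar (-3.35 to -2.05), sustentacular (-1.95 to -0.90) and erythroid genes (-2.57 to -1.28), and lay between -0.45 and 0.38 for horizontal basal cell, Bowman's gland and respiratory cilia genes. Swapped titles are consistent with the values and with the cell type field, but autofluorescent immune or supporting cells inside a GFP+ gate were not tested and could raise those markers too.

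Among 40 groups of 4 libraries for 10 genes, 6 held a library far from the other 3, where chance gives about 1 in 20. Kirrel2 was 16.76 in odor titled GFP- number 3, against 14.96 to 15.25. Number 3 was also highest for Kirrel2 in every other group, so this is not particular to that library. It held 16.11 in vehicle titled GFP-, 15.75 in odor titled GFP+ and 15.15 in vehicle titled GFP+. Olfr1099 was 9.05 in vehicle titled GFP+ number 4, against 9.78 to 9.85. Olfr1040 was 2.58 in vehicle titled GFP- number 2, against 2.99 to 3.06. Fos was 15.05 in vehicle titled GFP+ number 2, against 14.00 to 14.15. Gap43 was 6.22 in odor titled GFP- number 2, against 6.80 to 6.91. Cyp2g1 was 14.19 in odor titled GFP- number 4, against 12.57 to 12.74. Number 4 was also highest for Cyp2g1 in every other group. It held 13.54 in vehicle titled GFP-, 15.08 in odor titled GFP+ and 14.71 in vehicle titled GFP+, the last only just above the 14.68 of number 1.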

How the results depend on the processing

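Including unnamed probe sets and leaving out number 4 of both treatments were chosen after seeing the data. No call of a named gene reversed; Olfr1040 in libraries titled GFP-, which did not pass, went from 0.05 to -0.06 without odor pool 3 and -0.07 without vehicle pool 2. Between the gates, 1311 values of named genes in vehicle pools kept their side of the threshold, 50 lost it and 10 gained it, and in odor pools 1422, 45 and 22. The odor minus vehicle difference of Olfr16 ranged from 3.84 to 5.13 over 18 alternatives and passed in 10, with adjusted p over the list alone between 0.0021 and 0.177. Olfr1099 ranged from 2.09 to 2.62 and passed in 11 of 18, and Olfr1040 from 1.32 to 1.57 and passed in 11 of 17. In libraries titled GFP+, Olfr1099 passed in 19 of 19 alternatives, Olfr1040 in 17 of 18 and Olfr16 in 3 of 19. These tallies are adjusted over the list alone; over all genes 0 passed there without dim probe sets or without any 1 of 5 pools. The cause of the changes below was not tested, except that the dim filter kept 12936 genes and removed Olfr1040, and that leaving out pools lowers the number of samples. For the difference, 1 gene passed over all genes with the replicate block across treatments in place of the pool and 3 with the pool as a random block. The receptor count of 3 became 0 without dim probe sets and 5 with the replicate block, and 0 to 3 when a pool was left out. Gene lists went from 1 to 2 with the replicate block or with receptor centring, and 1 to 2 when a pool was left out. Gate counts ranged from 2402 to 3146 in vehicle pools and from 2570 to 3493 in odor pools when a pool was left out. Centring on the library median gave 6968 in odor pools, and 3756 in vehicle pools. For odor in libraries titled GFP+, the count of 2 became 1 with quantile normalization, array weights, the replicate block, the Y-linked covariate, receptor centring, unnamed probe sets or number 4 left out, 0 without dim probe sets, and 0 to 2 when a pool was left out. Its receptor count became 1 without dim probe sets or number 4, 8 with the replicate block, and 2 to 5 when a pool was left out. Its list count of 2 became 1 with median centring, without dim probe sets, with array weights or without number 4, and 1 to 4 when a pool was left out. For odor in libraries titled GFP-, 1 gene passed with trend and robust. Its receptor count of 2 became 0 with quantile normalization, median centring, unnamed probe sets or number 4 left out, 4 with trend and robust, 5 with array weights, 12 with the replicate block, 6 with the Y-linked covariate, and 0 to 3 when a pool was left out. In libraries titled GFP- the numbers correlated at 0.088 to 0.161, not all above the bound for pairing, although every library correlated best with its own number. With no replicate block the gates gave 2786 and 3078 genes in the fit of 16 libraries. With the replicate block, Olfr16 and Olfr1186, whose odor mean lay below background, gained the call in libraries titled GFP+ (adjusted p = 0.0403 and 0.0163 over the list alone, against 6.45e-05 to 0.47 over all alternatives for Olfr16), and Olfr1099 and Olfr1040 kept theirs over the list alone, but over all genes Olfr1040 lost its call (adjusted p = 0.0911). It changed no other call of a gene named there. In libraries titled GFP-, Olfr16 was among the 12 receptors with the block (adjusted p = 0.044) and the 6 with the Y-linked covariate (0.0341), against 0.0341 to 0.292 over 18 alternatives; it passed in 2. Kirrel2 lost its call between the gates without the pool block and with a random block (adjusted p = 0.145 and 0.0631 in vehicle pools), and Hspa1a with each of the other blocks. Signal near background limits Olfr1040, the vomeronasal receptors and most endothelial, stromal, horizontal basal cell, ensheathing glia and Bowman's gland genes.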

Other observations

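The test of receptor clusters and the genes named here were chosen after the values were seen.

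Single receptors differed far more between the gates than S100a5, or than Omp, whose values lay near the top of the arrays. In vehicle pools Olfr1507 had a log2 ratio of titled GFP- over titled GFP+ of -9.06, with group means of 5.26 and 14.32, and Olfr1213 of -8.99. At the other end Olfr481 stood at 5.49 and Olfr372 at 5.42. In odor pools the same receptors stood at -9.23, -8.69, 5.50 and 5.53. The titled GFP+ means of Olfr372 in both treatments and of Olfr481 in odor pools lay below the highest 95th percentile of vomeronasal genes there, 4.64 in vehicle and 4.57 in odor pools, so these ratios are lower bounds. The mean of Olfr481 in vehicle pools, 4.67, lay just above it. Trace amine receptors split as well: Taar2 was lower in vehicle pools (-2.93), as were Taar7f (-1.68) and Taar7a (-1.66), while Taar9 and Taar4 were higher.

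A hypothesis was that receptors of one genomic cluster share their gate ratio. Over 25 clusters of at least 8 receptors, with gaps of at most 1 Mb in the reference gene order, differences between clusters held 8.93% of the variance of 1029 receptors. None of 100000 random assignments gave as much (permutation p = 1e-05, the smallest they can give, highest 6.64%). The highest median was 1.78 over 8 receptors, from Olfr164 to Olfr171 on chromosome 16. The lowest was -1.45 over 15, from Olfr310 to Olfr292 on chromosome 7. Among larger clusters, that from Olfr522 to Olfr541 on chromosome 7 had a median of 1.64 over 19 receptors (quartiles 0.99 and 3.16). That from Olfr376 to Olfr412 on chromosome 11 had -1.19 over 30 (quartiles -3.35 and 0.14), with 8 above 0. Most of the variance lies within clusters, and shared probe binding among neighbours, which could give the same pattern as a permutation p of 1e-05, was not tested.

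Outside the lists of receptors, the immediate early gene Btg2 had an odor minus vehicle difference of -1.04 and the decoy interleukin receptor Il1r2 of -1.37, which had the smallest p over all genes and did not pass (limma adjusted p = 0.172); its means in the libraries titled GFP-, 4.02 and 3.95, lay below background. Among 2634 unnamed probe sets 0 passed for odor in either gate or for the difference (limma, with 113, 112 and 147 at an unadjusted p under 0.05), while 266 passed between the gates in vehicle pools and 244 in odor pools.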
